A study of Arabidopsis thaliana with 12 samples.

How the data were processed

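The count table holds, per the labels and the deposited table, raw read counts per gene, and a second deposited table holds TPM, a measure scaled to transcript length and library, for 36795 loci and 12 libraries. Per the labels, messenger RNA was captured on poly-T beads, fragmented and copied with random hexamer primers. The authors name fastp 0.23.1, HISAT2 2.2.1, HTSeq 2.0.5 and the genome build TAIR10, without settings for strand or multiply mapped reads. The count values were checked to be whole numbers, and the TPM columns were checked to have equal sums within rounding. The ratio of counts to TPM was proportional to the reference exon length within 1% for 99.98% of 8488 genes with at least 200 counts. Counts were used for all tests, and TPM only for an alternative fit.

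Gene names came from a reference annotation of the assembly TAIR10.1, used for names, overlapping genes and exon lengths, and no coordinates from it are given. Neighbouring genes were taken in the order of their locus numbers. Of the 36795 loci 36632 matched a locus tag there and 163 did not. No gene name in that annotation matched ODR1, so its transcript was not analysed here. For 11 list members the annotation holds no such symbol, and these were matched by locus.

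Genes were tested with the edgeR 4.0.16 quasi-likelihood test under R 4.3.3, with a robust estimate of the spread, TMM scaling and a filter on low counts (edgeR's filterByExpr by group, minimum count 10 and minimum total 15). This left 18413 genes. The 12 libraries entered 1 fit with 4 group means, and the 5 comparisons were contrasts of these means. Tests were two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05 on the adjusted p. The standard error of a log2 fold change is its absolute value divided by the square root of the F statistic. Library totals ran from 10060020 to 13693166 counts, and TMM factors from 0.960 to 1.03. The common biological coefficient of variation was 5.80%, and the median over genes was 7.66%. Chi-square per degree of freedom between replicates, where 1 is counting error alone, was 2.01 between Col-0 water replicates 1 and 2 and 5.75 between Col-0 mannitol replicates 1 and 2. Intervals and floors cover counting error only.

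The genes named were chosen by rule. The 10 genes NCED6, NCED9, CYP707A2, GA3OX1, DOG1, ABI5, bHLH57, EM6, RD29B and EXPA2 are given in each comparison whatever their result. To these come, per comparison, the 5 rising and the 5 falling calls with the largest absolute log2 fold change among genes with a mean of at least 10 CPM in a group compared and no overlap between the 2 groups, a condition that 10% of unchanged genes meet with 3 libraries against 3. For the interaction the condition on overlap was not used. From each list come up to 3 called members with the largest absolute log2 fold change and a mean of at least 1 CPM. Genes outside this rule are said to have been chosen after their values were seen.

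The lists are ABA biosynthesis, ABA catabolism, ABA signalling, ABA and osmotic response, LEA and seed maturation, seed storage protein and oil body, dormancy regulators, embryo programme transcription factors, gibberellin biosynthesis, gibberellin deactivation, gibberellin signalling, cell wall loosening, lipid mobilisation, photosynthesis, DNA replication and cell cycle, heat shock proteins, aquaporins, jasmonate, endosperm markers and seed coat markers. Added to these 20 by rule are the cytosolic ribosomal protein genes, the chloroplast-encoded genes and the mitochondrion-encoded genes. Lists with at least 3 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, and again with an estimated correlation. They were also tested with fry, which asks whether the genes of a list move on balance 1 way and does not compare them with other genes. Adjustment was over the 21 lists of a comparison. The design, the named-gene rule, the 20 lists, the 3 rules for lists and the alternatives were chosen before the data were examined.

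The alternatives were DESeq2 1.42.0 size factors within edgeR, upper-quartile and total count scaling, no filter on low counts, a stricter filter (at least 1 CPM in 3 libraries and a mean of 5 CPM or more), a replicate block, fits without chloroplast and mitochondrial genes, a spread not estimated robustly, the DESeq2 Wald test, limma-voom, limma-trend on log2 of TPM plus 1, fits of the 2 groups compared alone, a fold of at least 2, a stricter adjusted p of 0.01, and leaving out each library in turn. Lists of indolic glucosinolate, aliphatic glucosinolate, morning clock and evening clock genes were chosen after the data had been seen.

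The pipeline was tested on simulated data with 18413 genes, 100 of them changed at each fold. In the comparison of mannitol with water in Col-0 it recovered 74 of 100 genes changed 1.5-fold and 91 of 100 changed 2-fold, with 8 false calls. For the interaction it recovered 46 and 82, with 9 false calls. The changed genes were drawn from those with at least 20 expected counts at the mean library size. In the data 7798 genes were called in the first of these comparisons, so the false calls in simulation do not measure the error there. Of 20 random lists 1 was called in the first comparison and 0 for the interaction, and the changed list was called in both. Multiply mapped reads, splicing and sequence variants were not analysed here, since the tables hold counts per gene only.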

Results

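RNA sequencing of Arabidopsis thaliana seeds covered the wild type Col-0 and the mutant odr1-2, each in 2 imbibition media: water, the control, and 300 mM mannitol, applied as an osmotic stress. After-ripened seeds spent 2 days in the cold (4°C) before 12 h in the medium at issue, with 3 biological replicates in each of the 4 groups. The 12 libraries held between 10060020 and 13693166 gene counts each. Of 36795 loci, 18413 had enough counts to be tested, and these held at least 99.9% of the counts of each library. The transcript of ODR1 itself was not analysed here. Levels are given as counts per 1000000 counts of the library (CPM) with the SD over the 3 libraries of a group, and log2 fold changes with the standard error of the fit, with n = 3 per group throughout. A gene is said to have risen, fallen or differed only where the edgeR quasi-likelihood test gave an adjusted p under 0.05. Intervals, floors and counts cover counting error only, since reads were not tagged by molecule.

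The 4 groups were well apart in a principal component analysis of the genes tested. The first component held 51.2% of the variance and placed Col-0 in water at -59.8 and odr1-2 in mannitol at 58.9, with Col-0 in mannitol at 2.71 and odr1-2 in water at -1.85. The second component held 21.7% and placed Col-0 in mannitol at -40.3 and odr1-2 in water at 36.8. Chloroplast-encoded genes held 0.0109% of the counts in Col-0 in water, 0.0225% in Col-0 in mannitol, 0.00691% in odr1-2 in water and 0.0160% in odr1-2 in mannitol. The 10 most abundant genes of a library held on average 4.94%, 6.43%, 6.57% and 8.24% in the same order of groups. Some genes named in the text share annotated sequence with a tested gene on the other strand that reached at least 10% of their level, and the strand setting of the counts is not stated. Among these are XTH15 with AT4G14120, AT1G64795 with ILA, MRD1 with HEI10, TIP3;1 with AT1G73200, TIP3;2 with AT1G05333, MFT with AT1G05383, MCM7 with STP7, HSP17.4 with AT3G07365 and ABF4 with AT3G03815.

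**Figure D1:**
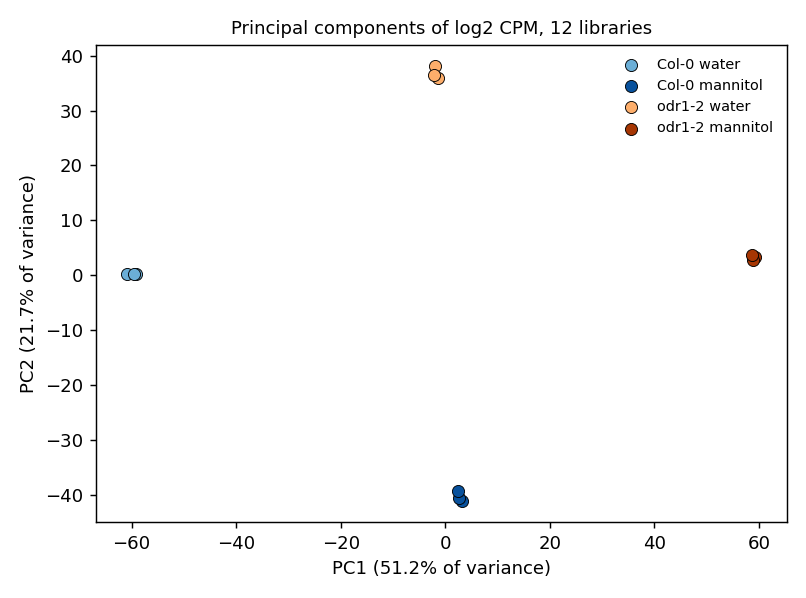
First and second principal components of log2 CPM, one point per library, coloured by group. The 3 libraries of each group lie together, and odr1-2 in water (-1.85) and Col-0 in mannitol (2.71) lie at nearby places on the first axis but on opposite sides of the second (36.8 and -40.3).

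The first comparison asked how wild-type seeds responded to mannitol. In Col-0 all 22 LEA and seed maturation genes rose and 13 of 19 cell wall loosening genes fell. DOG1 (AT5G45830), a central regulator of seed dormancy, rose from 1.29 ± 0.455 CPM in water to 9.16 ± 1.18 CPM in mannitol, a log2 fold change of 2.82 ± 0.21. RD29B, a marker of abscisic acid (ABA) response, rose from 62.2 ± 4.84 to 199 ± 3.79 CPM, and EM6, which encodes a late embryogenesis abundant (LEA) protein, from 256 ± 12.6 to 997 ± 93.2 CPM. GA3OX1, which encodes an enzyme of the last step to active gibberellin, fell from 36.2 ± 0.874 to 8.43 ± 2.35 CPM. XTH15, which encodes an enzyme that remodels xyloglucan in the cell wall, fell from 125 ± 4.85 to 6.79 ± 2.04 CPM.

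Among the other genes fixed in advance, NCED9, which encodes an enzyme of ABA synthesis, rose by 1.61 ± 0.12 on the log2 scale and ABI5, a transcription factor of ABA signalling, by 0.42 ± 0.06. NCED6, of the same enzyme family as NCED9, fell by 0.84 ± 0.21. CYP707A2, which encodes an ABA-inactivating hydroxylase, fell by 0.21 ± 0.07, a call that was lost without Col-0 water replicate 1 (log2 fold change -0.15) and without Col-0 mannitol replicate 3 (-0.15). The transcription factor gene bHLH57 had a log2 fold change of 0.29 ± 0.18 that missed the threshold in all 12 libraries and passed it without Col-0 mannitol replicate 3 (0.51). EXPA2, an expansin gene, stood at 620 ± 1.07 CPM in water and 603 ± 12.8 CPM in mannitol and was not called (-0.04 ± 0.04), although the limma-trend fit on TPM called it (-0.10).

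The 5 largest rises among genes with at least 10 CPM in one of the 2 groups were those of GASA2 (3.37 ± 0.11), of the galactinol synthase gene GOLS2 (3.04 ± 0.15), of AT5G55135 (2.78 ± 0.16), of the maturation gene ECP31 (2.71 ± 0.05) and of the histone family gene AT1G08170 (2.68 ± 0.12). The 5 largest falls were those of XTH33 (-5.09 ± 0.35), XTH4 (-4.52 ± 0.27), XTH9 (-4.31 ± 0.12), EXO (-4.29 ± 0.12) and XTH15 (-4.20 ± 0.10).

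All 22 tested members of the LEA and seed maturation list rose in Col-0, with a median log2 fold change of 1.41, among them ECP31, EM1 (2.06 ± 0.09) and EM6 (1.96 ± 0.06). All 18 tested members of the seed storage protein and oil body list rose as well, with a median of 1.46, among them SESA5 (2.39 ± 0.04) and AT2G18540 (1.95 ± 0.07). Of 16 ABA and osmotic response genes, 7 rose and 3 fell, and the largest rises were those of GOLS2, RAB18 (1.84 ± 0.10) and LTI30 (1.84 ± 0.13). Of 8 ABA biosynthesis genes, 3 rose and 1 fell, with ABA1 up by 0.99 ± 0.06. Of 23 ABA signalling genes, 12 rose and 4 fell, with AFP3 up by 1.83 ± 0.36, HAI3 up by 1.21 ± 0.06 and ABI4 down (-1.26 ± 0.07). Both tested ABA catabolism genes fell, CYP707A3 by more (-1.90 ± 0.32) than CYP707A2. Of 14 dormancy regulators, 8 rose and 3 fell, and MFT (1.42 ± 0.06) and DOGL4 (1.35 ± 0.07) rose beside DOG1. Of 12 heat shock protein genes, 8 rose and 0 fell, among them the chaperone genes HSP101 (1.58 ± 0.10) and HSP17.4 (0.97 ± 0.06).

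Of 19 cell wall loosening genes, 13 fell and 2 rose in Col-0, and XTH33, XTH4 and XTH9 fell most. Of 16 DNA replication and cell cycle genes, 9 fell and 0 rose. Among the called members with a mean of at least 1 CPM in either group, the replicative helicase genes MCM7 (-1.54 ± 0.14), MCM6 (-1.35 ± 0.16) and MCM3 (-1.31 ± 0.14) fell most. Among 10 gibberellin biosynthesis genes, 3 rose and 2 fell, and the 2 that fell were GA3OX1 and GA3OX2 (-1.87 ± 0.10), whereas GA20OX3 rose by 0.44 ± 0.05. The 1 tested gibberellin deactivation gene, GA2OX2, rose by 0.59 ± 0.16. Of 9 gibberellin signalling genes, 3 rose and 4 fell, with GID1C (0.87 ± 0.14) and GID1A (0.83 ± 0.07), which encode receptors, up and RGL1 down (-1.15 ± 0.23). Among 8 aquaporin genes, 3 rose and 3 fell: the seed tonoplast genes TIP3;2 (2.46 ± 0.05) and TIP3;1 (1.88 ± 0.04) rose and the plasma membrane gene PIP2;8 fell (-1.32 ± 0.22). Of 18 lipid mobilisation genes, 7 rose and 1 fell, with ICL, the isocitrate lyase gene, up by 0.43 ± 0.03.

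Counts of chloroplast-encoded genes rose in Col-0 for 36 of 42 genes, with a median log2 fold change of 1.52, while their share of all counts stayed at 0.0225% or less on average in every group. Here and in the later comparisons, counts of chloroplast- and mitochondrion-encoded genes cover only RNA captured on poly-T beads. A change in capture cannot be told apart from a change in level. Of 8 mitochondrion-encoded genes, 3 rose and 0 fell, with ATMG00090 up by 1.40 ± 0.19. Of 272 cytosolic ribosomal protein genes, 156 fell and 9 rose, with a median of -0.17. Of 20 photosynthesis genes, 3 rose and 3 fell, with LHCB4.1 up (0.94 ± 0.07) and RBCS2B down (-1.73 ± 0.20). Of 6 embryo programme transcription factors, 2 rose and 1 fell, with ABI3 up by 0.26 ± 0.05, and the 1 fall, that of VAL2, was lost without Col-0 water replicate 1 (-0.19) or Col-0 mannitol replicate 2 (-0.16). Of 5 jasmonate genes, 1 rose, AOS (0.87 ± 0.25), and 1 fell, JAZ1 (-0.74 ± 0.15). Of 4 endosperm markers, 1 rose, MAN7 (0.50 ± 0.05), and 0 fell. Of 3 seed coat markers, 1 fell, GL2, a call lost without any 1 of Col-0 water replicate 2 (-0.46), Col-0 water replicate 3 (-0.49) and Col-0 mannitol replicate 2 (-0.38).

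Across all 18413 genes, 7798 were called in Col-0, 3865 up and 3933 down, and 1443 of these changed by at least 2-fold, 748 up and 695 down. The near-even split depended on the scaling: 3412 rose and 4434 fell with total count scaling, and 3054 rose and 4388 fell in the limma-trend fit on TPM. The list test (camera) called 10 of 21 lists, of which 6 held with an estimated correlation: LEA and seed maturation (adjusted p = 0.0166 with an estimated correlation), seed storage protein and oil body (0.000360), dormancy regulators (0.0414), heat shock proteins (0.0152), chloroplast-encoded (0.00947) and cell wall loosening (0.0128). The calls of ABA signalling (adjusted p = 0.0968 with an estimated correlation), DNA replication and cell cycle (0.0544), cytosolic ribosomal protein (0.365) and mitochondrion-encoded genes (0.0608) did not. Camera did not call the other 11 lists, among them ABA and osmotic response (adjusted p = 0.0557) and ABA biosynthesis (0.101). Adjusted over the list alone, the counts equalled those over all genes tested, except for ABA signalling (13 up), chloroplast-encoded (37 up), jasmonate (2 up, 2 down), photosynthesis (2 down) and cytosolic ribosomal protein (11 up, 164 down). For gibberellin biosynthesis the median was positive (0.19) and the mean negative (-0.21), and for aquaporins the median was negative (-0.13) and the mean positive (0.22).

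**Figure D2:**
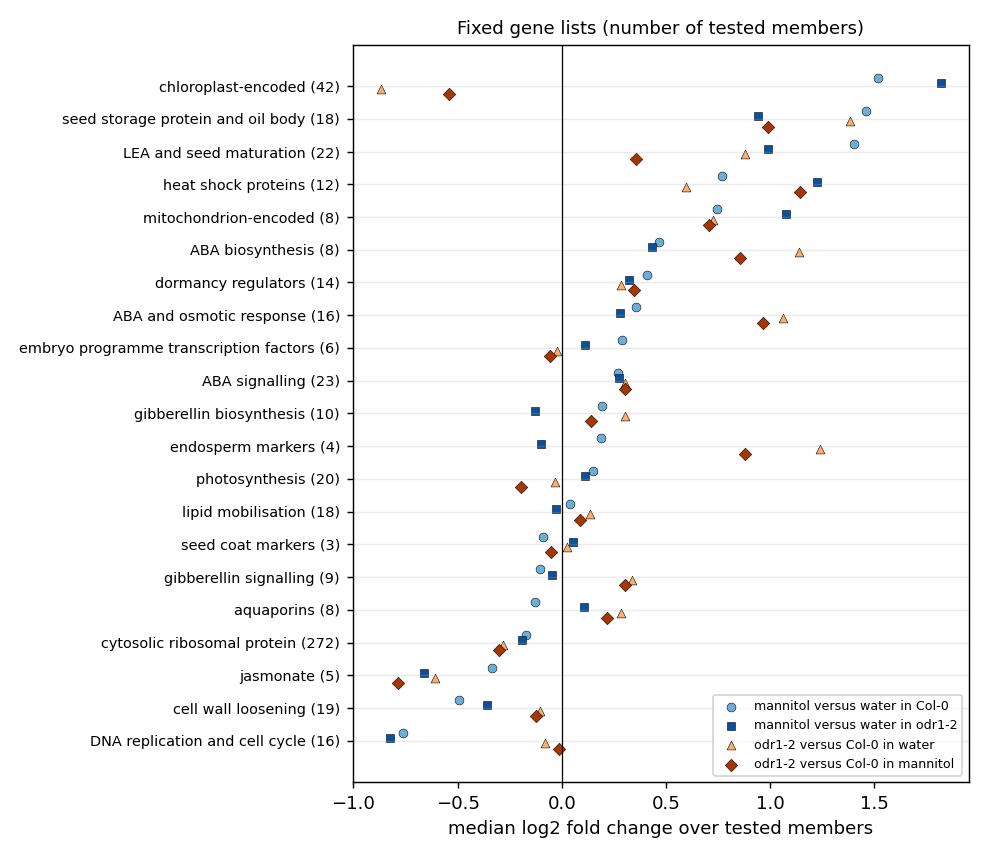
Median log2 fold change of the tested members of each gene list fixed in advance, one symbol per comparison, with the number of tested members in brackets. The maturation lists lie to the right in all 4 comparisons, and the chloroplast-encoded list lies to the right for mannitol (1.52 and 1.82) and to the left for odr1-2 (-0.87 and -0.54). Under another scaling the median changes sign for seed coat markers in odr1-2 versus Col-0 in water (upper quartile, TPM) and in mannitol versus water in odr1-2 (total count, TPM), for lipid mobilisation in Col-0 (TPM) and for photosynthesis in odr1-2 (TPM).

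The second comparison asked how odr1-2 seeds responded to mannitol. The same 22 LEA and seed maturation genes rose here too, and 13 of 19 cell wall loosening genes fell. DOG1 rose from 10.3 ± 0.936 to 35.3 ± 2.45 CPM, EM6 from 454 ± 35.4 to 1302 ± 27.1 CPM, and RD29B from 260 ± 10.8 to 402 ± 14.2 CPM. GA3OX1 fell from 60.4 ± 1.48 to 23.4 ± 1.11 CPM, and XTH15 from 121 ± 4.70 to 2.34 ± 0.202 CPM.

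NCED9 rose by 0.88 ± 0.10 on the log2 scale in odr1-2 and ABI5 by 0.38 ± 0.06, while NCED6 fell by 0.77 ± 0.17 and EXPA2 by 0.36 ± 0.04. CYP707A2 stood at 123 ± 7.61 CPM in water and 131 ± 5.62 CPM in mannitol and was not called (0.09 ± 0.06). The rise of bHLH57 (0.48 ± 0.17) was lost without odr1-2 water replicate 2 (0.43), without odr1-2 mannitol replicate 1 (0.45) and in the limma-trend fit on TPM (0.33). Among genes with a mean of at least 10 CPM in either group, the largest rises included AT1G08170 (2.54 ± 0.11), GASA2 (2.45 ± 0.07), SEN1 (2.25 ± 0.18) and GOLS2 (2.22 ± 0.11). AT5G66230, a chalcone isomerase family gene, headed these rises (3.36 ± 1.03) with uneven libraries, 4.53 ± 7.49 CPM in water and 48.4 ± 39.9 CPM in mannitol. That call was lost in limma-voom (5.31), in the fit of the 2 groups alone (3.35), and without odr1-2 water replicate 1 (2.88), odr1-2 water replicate 3 (2.75) or odr1-2 mannitol replicate 2 (2.44). Within the same limit, the largest falls were those of XTH15 (-5.69 ± 0.12), EXO (-5.63 ± 0.14), AT4G14120 (-4.99 ± 0.15), XTH4 (-4.74 ± 0.29) and the lipase family gene AT5G45670 (-3.83 ± 0.18). XTH33 had 0 counts in the 3 mannitol libraries and 81 in the 3 water libraries of odr1-2, so that it was at least 23.7-fold lower against a floor of 3 counts over the group.

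In odr1-2 all 22 LEA and seed maturation genes and all 18 storage protein and oil body genes rose, with medians of 0.99 and 0.94, among them HSFA9 (1.98 ± 0.18), ECP31 (1.91 ± 0.04), SESA5 (1.60 ± 0.04), CRU4 (1.41 ± 0.09) and OLEO4 (1.36 ± 0.05). Of 12 heat shock protein genes, 11 rose and 0 fell, with HSP101 up by 1.94 ± 0.07 and HSP17.6A by 1.84 ± 0.08. ABA and osmotic response genes rose in 7 and fell in 3 of 16 cases, with RAB18 up by 1.73 ± 0.10. ABA biosynthesis genes rose in 5 and fell in 1 of 8 cases, and ABA signalling genes rose in 14 and fell in 3 of 23, with ABF4 up by 1.17 ± 0.09. Of the 2 ABA catabolism genes, CYP707A3 fell (-1.91 ± 0.30). Of 14 dormancy regulators, 8 rose and 2 fell, with DOGL4 up by 0.86 ± 0.07 and MFT by 0.83 ± 0.06. Chloroplast-encoded genes rose in 36 of 42 cases (median 1.82) and mitochondrion-encoded genes in 5 of 8 (median 1.08), with 0 falls in either list.

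Cell wall loosening genes fell in 13 of 19 cases with 0 rises in odr1-2, and DNA replication and cell cycle genes fell in 11 of 16 with 0 rises, among them PCNA1 (-1.51 ± 0.19) and MCM6 (-1.43 ± 0.17). Of 10 gibberellin biosynthesis genes, 2 rose and 4 fell, with GA3OX2 (-1.14 ± 0.08) and GA20OX2 (-1.11 ± 0.23) beside GA3OX1. GA2OX2 rose by 0.45 ± 0.14, a call lost in the limma-trend fit on TPM (0.32). Among gibberellin signalling genes 3 rose and 3 fell of 9, with GID1C (0.89 ± 0.13) and GID1A (0.89 ± 0.07) up and RGL1 down (-0.77 ± 0.19). Ribosomal protein genes fell in 166 and rose in 10 of 272 cases. Lipid mobilisation genes rose in 5 and fell in 6 of 18 cases, photosynthesis genes rose in 2 and fell in 3 of 20, and aquaporin genes rose in 3 and fell in 3 of 8, with TIP3;2 up (1.61 ± 0.04) and PIP2;7 down (-1.14 ± 0.05). Of 5 jasmonate genes 1 rose and 2 fell, of 6 embryo programme transcription factors 1 rose and 1 fell, of 4 endosperm markers 2 fell, EXPA2 and ICE1 (-0.19 ± 0.05), and of 3 seed coat markers 1 fell, GL2 (-0.76 ± 0.21). Some of these calls were lost in other fits: the rise of AOS without odr1-2 water replicate 1 (0.74) or odr1-2 mannitol replicate 1 (0.92), and the fall of JAZ10 without odr1-2 water replicate 2 (-0.80) or 3 (-0.65) or odr1-2 mannitol replicate 1 (-0.81) or 3 (-0.60). So were the fall of WRI1 without odr1-2 water replicate 1 (-0.35) or odr1-2 mannitol replicate 1 (-0.53) or 3 (-0.67) and in limma-voom (-0.56), and the rise of ABI3 with total count scaling (0.12) and in the limma-trend fit on TPM (0.09).

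In odr1-2 mannitol changed 7826 genes, 3907 up and 3919 down, and 1217 by at least 2-fold, 565 up and 652 down. The split by direction depended on the scaling: 3068 rose and 4957 fell with total count scaling, and 2511 rose and 5122 fell in the limma-trend fit on TPM. Camera called 11 of 21 lists and 7 held with an estimated correlation: LEA and seed maturation (adjusted p = 0.0187 with an estimated correlation), seed storage protein and oil body (0.000610), heat shock proteins (0.00211), cell wall loosening (0.00282), DNA replication and cell cycle (0.0187), chloroplast-encoded (0.00211) and mitochondrion-encoded (0.0187). The calls of ABA and osmotic response (adjusted p = 0.0862 with an estimated correlation), ABA signalling (0.0832), dormancy regulators (0.0544) and cytosolic ribosomal protein (0.325) were lost. Adjusted over the list alone, the counts equalled those over all genes tested except for ABA and osmotic response (8 up), ABA signalling (15 up), cell wall loosening (14 down), chloroplast-encoded (38 up), dormancy regulators (3 down), mitochondrion-encoded (6 up) and cytosolic ribosomal protein (11 up, 176 down).

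The third comparison asked how odr1-2 differed from Col-0 in water, without the osmotic stress. All 22 LEA and seed maturation genes, 16 of 18 storage protein and oil body genes and 14 of 23 ABA signalling genes were higher in the mutant. FUS3, a transcription factor of the embryo maturation programme, stood at 1.38 ± 0.240 CPM in Col-0 and 22.8 ± 0.791 CPM in odr1-2 (4.04 ± 0.18). DOG1 was higher by 2.98 ± 0.21 on the log2 scale, RD29B by 2.06 ± 0.05, NCED9 by 1.29 ± 0.12 and NCED6 by 1.03 ± 0.18. CYP707A2 (58.2 ± 4.83 against 123 ± 7.61 CPM) and EXPA2 (620 ± 1.07 against 1277 ± 38.1 CPM) were higher in odr1-2 as well. GA3OX1 was higher by 0.74 ± 0.09, while GA20OX2, which encodes an earlier enzyme of gibberellin synthesis, was lower, at 15.2 ± 0.194 CPM in Col-0 and 4.11 ± 0.662 CPM in odr1-2.

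EM6 was higher in odr1-2 in water by 0.83 ± 0.06 and ABI5 by 0.20 ± 0.06, and bHLH57 (0.29 ± 0.18) was not called. Among genes with a mean of at least 10 CPM in either group, the largest differences were at loci nearly silent in Col-0. AT2G11410 had 0 counts in the 6 Col-0 libraries, and against a floor of 3 counts over the group it was at least 301-fold higher in odr1-2 in water. SADHU8-1, named after a family of retroelements, had 1 count in the Col-0 water libraries and 725 in those of odr1-2, a ratio of 698 with a 95% exact interval from 125 to 27620. The metal transporter gene IRT3 (6.79 ± 0.29), AT1G64795 (6.53 ± 0.13) and AT1G67105 (4.56 ± 0.24) followed. Within the same limit, the 5 largest falls were those of MRD1, at 54.4 ± 2.87 CPM in Col-0 and 0.657 ± 0.209 CPM in odr1-2 (-6.36 ± 0.17), AT5G26220 (-4.06 ± 0.32), CYP83B1, a gene of indolic glucosinolate synthesis (-2.45 ± 0.10), XTH33 (-2.26 ± 0.25) and IGMT5 (-2.26 ± 0.08).

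All 22 LEA and seed maturation genes were higher in odr1-2 in water (median 0.88), with LEA7 (1.94 ± 0.04), ECP31 (1.75 ± 0.05) and PER1 (1.71 ± 0.04) in front. Of 18 storage protein and oil body genes, 16 were higher and 1 lower (median 1.38), with the oleosin gene OLEO2 (2.15 ± 0.04) and the albumin gene SESA2 (2.15 ± 0.05) in front. Of 8 ABA biosynthesis genes, 6 were higher and 0 lower, among them NCED3 (1.70 ± 0.28) and NCED5 (1.62 ± 0.28). Of 16 ABA and osmotic response genes, 10 were higher, with GOLS2 in front, and 1 was lower, RD22 (-1.84 ± 0.29). Of 23 ABA signalling genes, 14 were higher and 0 lower, including the phosphatase genes HAI3 (1.53 ± 0.06) and AHG1 (1.40 ± 0.05). Of the 2 ABA catabolism genes, CYP707A2 was higher (1.08 ± 0.07). Of 14 dormancy regulators, 8 were higher and 1 lower, with MFT at 1.49 ± 0.06. Of 4 endosperm markers, 3 were higher and 0 lower: MAN7 (1.55 ± 0.05), EPR1 (1.44 ± 0.21) and EXPA2 (1.04 ± 0.04). Of 12 heat shock protein genes, 7 were higher, among them HSP101 (1.89 ± 0.10) and HSP70 (1.47 ± 0.04), and 3 were lower, among them HSP17.8 (-1.69 ± 0.49).

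Of 272 ribosomal protein genes, 219 were lower and 6 higher in odr1-2 in water, with a median of -0.28. Chloroplast-encoded genes were lower in 18 of 42 cases and higher in 0 (median -0.87), and mitochondrion-encoded genes were higher in 4 and lower in 1 of 8. Among 10 gibberellin biosynthesis genes, 5 were higher and 3 lower (4 and 4 with upper-quartile or total count scaling), and GA20OX2 (-1.90 ± 0.17) and GA20OX1 (-1.56 ± 0.26) were lower. GA2OX2 was higher by 0.86 ± 0.15. Of 9 gibberellin signalling genes, 6 were higher and 1 lower, with the growth repressor gene RGA at 0.49 ± 0.05. Of 5 jasmonate genes, 2 were lower and 0 higher: AOS (-2.02 ± 0.33) and OPR3 (-1.25 ± 0.21), both of jasmonate synthesis. Of 19 cell wall loosening genes, 4 were higher, with MAN7 in front, and 8 lower, with EXPA15 at -1.34 ± 0.05. Of 8 aquaporin genes, 4 were higher and 2 lower (3 and 3 with upper-quartile scaling), and TIP3;1 was higher by 2.37 ± 0.04. Of 16 DNA replication and cell cycle genes, 3 were higher, with CYCD1;1 at 1.02 ± 0.32, and 6 lower, with PCNA2 at -0.51 ± 0.10. Of 18 lipid mobilisation genes, 10 were higher, with AIM1 at 0.58 ± 0.05, and 2 lower. Of 20 photosynthesis genes, 7 were higher, with PSBO1 at 1.87 ± 0.16, and 2 lower. FUS3 was the 1 called member of the 6 embryo programme transcription factors, and GL2 (-0.61 ± 0.18) that of the 3 seed coat markers.

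In water 7182 genes differed between the genotypes, 3757 higher and 3425 lower in odr1-2, and 1193 differed by at least 2-fold, 864 higher and 329 lower. The larger side turned with the scaling, to 3255 higher and 4167 lower with upper-quartile scaling and 3526 and 3752 with total count scaling. Camera called 12 of 21 lists and 8 held with an estimated correlation: LEA and seed maturation (adjusted p = 0.0273 with an estimated correlation), seed storage protein and oil body (0.000760), ABA and osmotic response (0.0152), ABA biosynthesis (0.0171), ABA signalling (0.0171), dormancy regulators (0.0273), endosperm markers (0.0404) and chloroplast-encoded (0.0171). The calls of heat shock proteins (adjusted p = 0.0582 with an estimated correlation), gibberellin signalling (0.139), lipid mobilisation (0.139) and cytosolic ribosomal protein (0.132) were lost. Adjusted over the list alone, the counts equalled those over all genes tested except for ABA signalling (15 up), aquaporins (5 up, 3 down), endosperm markers (1 down), gibberellin biosynthesis (4 down), lipid mobilisation (11 up, 3 down) and cytosolic ribosomal protein (7 up, 229 down).

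**Figure D3:**
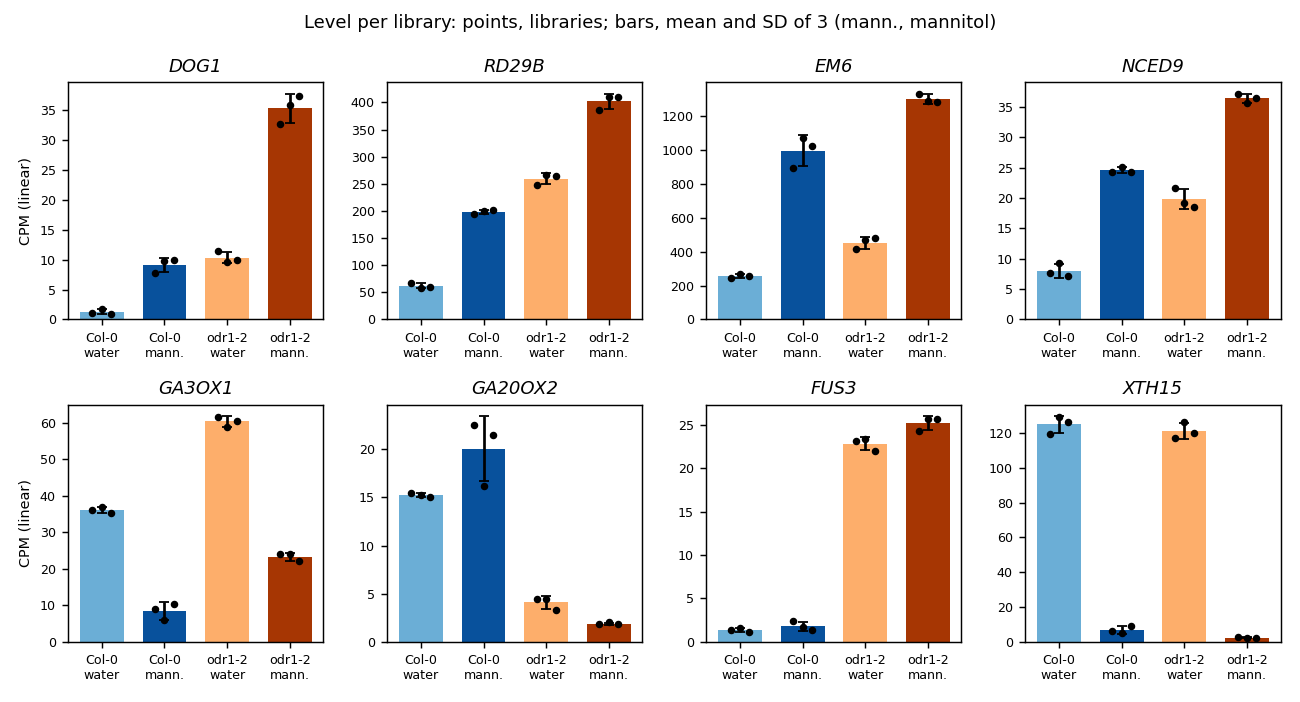
CPM on a linear scale for 8 genes, with points for single libraries and bars for the mean and SD of the 3 libraries of a group. DOG1 rose with mannitol in both genotypes and reached 35.3 CPM in odr1-2, FUS3 stood at 22.8 and 25.2 CPM in odr1-2, and GA20OX2 was lower in odr1-2 in water (4.11 CPM) and in mannitol (1.88 CPM) than in Col-0.

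The fourth comparison asked how odr1-2 differed from Col-0 in mannitol. FUS3 was again higher, by 3.80 ± 0.18 on the log2 scale, and DOG1 by 1.94 ± 0.13, GA3OX1 by 1.47 ± 0.12 and CYP707A2 by 1.38 ± 0.07. GA20OX2 stood at 20.1 ± 3.38 CPM in Col-0 and 1.88 ± 0.117 CPM in odr1-2, a log2 fold change of -3.40 ± 0.19. HSP101 stood at 31.8 ± 4.73 CPM in Col-0 and 151 ± 3.87 CPM in odr1-2, and HSP70 at 323 ± 6.92 and 918 ± 7.06 CPM.

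RD29B was higher in odr1-2 in mannitol by 1.02 ± 0.05, EXPA2 by 0.72 ± 0.04, NCED9 by 0.57 ± 0.10 and EM6 by 0.38 ± 0.06. NCED6 was higher as well, at 3.35 ± 0.202 CPM in Col-0 and 7.20 ± 1.64 CPM in odr1-2. ABI5 was higher by 0.16 ± 0.06, a call lost with upper-quartile scaling (0.10), with total count scaling (0.11), in the limma-trend fit on TPM (0.09), and without Col-0 mannitol replicate 1 (0.13) or odr1-2 mannitol replicate 1 (0.10). bHLH57 was higher by 0.48 ± 0.17, a call lost in the limma-trend fit on TPM (0.41) and without Col-0 mannitol replicate 1 (0.44) or 3 (0.26) or odr1-2 mannitol replicate 1 (0.45) or 3 (0.47). Among genes with a mean of at least 10 CPM in either group, AT2G11410 and SADHU8-1 differed most. AT2G11410 was at least 279-fold higher and SADHU8-1 at least 268-fold higher in odr1-2, each against a floor of 3 counts over the group. AT1G64795 (6.45 ± 0.10), IRT3 (5.35 ± 0.30) and AT5G55620 (5.18 ± 0.29) followed. Within the same limit, MRD1 (-5.82 ± 0.17), GA20OX2, the transporter family gene SIAR1 (-3.31 ± 0.17), IGMT5 (-2.79 ± 0.11) and KUOX1 (-2.62 ± 0.18) were lowest.

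Of 22 LEA and seed maturation genes, 16 were higher in odr1-2 in mannitol and 0 lower (median 0.36), with LEA7 at 1.27 ± 0.04 and HSFA9 at 1.08 ± 0.17. Of 18 storage protein and oil body genes, 16 were higher and 1 lower (median 0.99), with SESA2 at 1.89 ± 0.04 and CLO1 at 1.47 ± 0.05. Of 12 heat shock protein genes, 9 were higher and 0 lower (median 1.14), with HSP101 at 2.25 ± 0.08 and HSP90.1 at 1.87 ± 0.08. Of 8 ABA biosynthesis genes, 6 were higher and 0 lower, with NCED3 at 2.64 ± 0.31. Of 16 ABA and osmotic response genes, 11 were higher, with HB12 at 2.90 ± 0.66 and COR47 at 1.51 ± 0.08, and 1 was lower, RD22 (-2.61 ± 0.35). Of 23 ABA signalling genes, 12 were higher and 0 lower, with AHG1 at 1.37 ± 0.05 and ABI4 at 1.26 ± 0.07, and the kinase gene SNRK2.6 was among them. CYP707A2 was the 1 called member of the 2 ABA catabolism genes. Of 14 dormancy regulators, 8 were higher, with MFT at 0.89 ± 0.06, and 2 lower, with ERF12 at -0.99 ± 0.09. Of 4 endosperm markers, 3 were higher, with EPR1 at 1.35 ± 0.21, and 1 lower.

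Ribosomal protein genes were lower in odr1-2 in mannitol in 215 and higher in 5 of 272 cases (median -0.30), and chloroplast-encoded genes were lower in 13 and higher in 0 of 42 (median -0.54). Mitochondrion-encoded genes were higher in 6 and lower in 0 of 8. Gibberellin biosynthesis genes were higher in 3 and lower in 3 of 10, with GA20OX1 at -2.31 ± 0.29, and GA2OX2 was higher by 0.72 ± 0.14. Gibberellin signalling genes were higher in 6 and lower in 1 of 9, with RGL1 at 0.95 ± 0.23 and RGA at 0.78 ± 0.05. Jasmonate genes were lower in 3 and higher in 0 of 5, with AOS at -1.81 ± 0.28 and OPR3 at -1.81 ± 0.22. DNA replication and cell cycle genes were lower in 3 of 16 and higher in 0, with RNR1 at -0.86 ± 0.05. Photosynthesis genes were higher in 6 and lower in 2 of 20, with PSBO1 at 1.94 ± 0.16. Cell wall loosening genes were higher in 7 and lower in 6 of 19, lipid mobilisation genes higher in 5 and lower in 4 of 18, and aquaporin genes higher in 3 and lower in 1 of 8. With upper-quartile or total count scaling these became 6 and 7, 3 and 5, and 2 and 2. The call of the aquaporin gene PIP2;8 was also lost without Col-0 mannitol replicate 2 (0.48) or 3 (0.50), odr1-2 water replicate 3 (0.59) or odr1-2 mannitol replicate 1 (0.53), 2 (0.59) or 3 (0.65), and that of JAZ10 without Col-0 mannitol replicate 2 (-0.77) or 3 (-0.75) or odr1-2 mannitol replicate 1 (-0.80) or 3 (-0.59). Embryo programme transcription factors were higher in 1 case, FUS3, and lower in 1, VAL1 (-0.30 ± 0.07), and GL2 (-0.87 ± 0.21) was the 1 seed coat marker called.

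In mannitol 7382 genes differed between the genotypes, 3779 higher and 3603 lower in odr1-2, and 1255 by at least 2-fold, 835 higher and 420 lower. With upper-quartile scaling 3134 were higher and 4565 lower, and in the limma-trend fit on TPM 2909 were higher and 4242 lower. Camera called 11 of 21 lists and 5 held with an estimated correlation: seed storage protein and oil body (adjusted p = 0.00307 with an estimated correlation), heat shock proteins (0.00531), ABA and osmotic response (0.0108), ABA biosynthesis (0.0259) and ABA signalling (0.0259). The calls of LEA and seed maturation (adjusted p = 0.121 with an estimated correlation), cytosolic ribosomal protein (0.121), chloroplast-encoded (0.0996), mitochondrion-encoded (0.0560), endosperm markers (0.108) and gibberellin signalling (0.126) were lost. Adjusted over the list alone, the counts equalled those over all genes tested except for ABA and osmotic response (12 up), ABA biosynthesis (7 up), LEA and seed maturation (17 up), cell wall loosening (8 up, 7 down), heat shock proteins (10 up), embryo programme transcription factors (2 down), lipid mobilisation (7 up), photosynthesis (3 down) and cytosolic ribosomal protein (7 up, 225 down). Medians and means differed in sign for gibberellin biosynthesis in both media, for photosynthesis and embryo programme transcription factors in both media, and for seed coat markers in water.

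The fifth comparison asked whether the 2 genotypes differed in their response to mannitol, by the interaction of genotype and treatment. Most storage and LEA genes, which rose in both genotypes, had a smaller fold change in odr1-2, and 4 of 12 heat shock protein genes had a more positive response there. Of 22 LEA and seed maturation genes, 18 had a negative interaction and 0 a positive one (median -0.43), with ECP31 at -0.80 ± 0.06 and PER1 at -0.75 ± 0.06. Of 18 storage protein and oil body genes, 13 had a negative interaction and 1 a positive one (median -0.50), with AT2G18540 at -1.02 ± 0.10. Of 12 heat shock protein genes, 4 had a positive interaction and 0 a negative one (median 0.32), with HSP17.6A at 1.11 ± 0.12.

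As a fold change RD29B rose less in odr1-2 (interaction -1.05 ± 0.07), as did NCED9 (-0.73 ± 0.16) and EM6 (-0.44 ± 0.08), and EXPA2 had an interaction of -0.32 ± 0.06. DOG1 also rose less on the log2 scale (-1.04 ± 0.27), a call lost without Col-0 water replicate 1 (-0.96) or 3 (-0.83), in limma-voom (-1.05) and in the limma-trend fit on TPM (-0.50). As a fold change GA3OX1 fell less in odr1-2 (0.73 ± 0.15), a call lost in the limma-trend fit on TPM (0.63), and GA3OX2 did so too (0.74 ± 0.13). The interactions of CYP707A2 (0.30 ± 0.09), ABI5 (-0.04 ± 0.08), NCED6 (0.07 ± 0.27) and bHLH57 (0.19 ± 0.25) were not called, although that of CYP707A2 passed the threshold with no filter on low counts (0.30), a stricter filter (0.30) or a replicate block (0.30), and without Col-0 water replicate 2 (0.35), Col-0 mannitol replicate 1 (0.37) or 2 (0.29), odr1-2 water replicate 1 (0.35) or odr1-2 mannitol replicate 3 (0.33). Among genes with a mean of at least 10 CPM in any group, the largest positive interactions were those of FTM1 (2.00 ± 0.27), the glutathione transferase gene GSTF9 (1.35 ± 0.10), ATCG00340 (1.33 ± 0.37), YLS5 (1.32 ± 0.21) and AT4G30470 (1.31 ± 0.20). FTM1 fell from 22.0 ± 2.25 to 3.41 ± 0.981 CPM in Col-0 and from 6.24 ± 0.492 to 3.89 ± 0.287 CPM in odr1-2. The call of ATCG00340 was lost without Col-0 water replicate 1 (1.29), odr1-2 water replicate 2 (1.07) or 3 (1.37) or odr1-2 mannitol replicate 3 (1.21), and in limma-voom (1.36) and the limma-trend fit on TPM (0.45). Within the same limit on level, the largest negative interactions were those of AT2G29310 (-2.42 ± 0.46), GA20OX2 (-1.50 ± 0.27), XTH15 (-1.49 ± 0.20), CYP78A6 (-1.47 ± 0.30) and AT5G45670 (-1.45 ± 0.27).

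Among the other lists, dormancy regulators had 5 negative and 0 positive interactions of 14 (median -0.10), with MFT at -0.59 ± 0.09, and endosperm markers 2 negative and 0 positive of 4 (median -0.24), with MAN7 at -0.51 ± 0.07. Lipid mobilisation genes had 4 negative and 0 positive of 18 (median -0.11), with PMDH1 at -0.24 ± 0.06, and chloroplast-encoded genes 2 positive and 0 negative of 42 (median 0.46). The aquaporin genes TIP3;1 (-0.94 ± 0.05) and TIP3;2 (-0.85 ± 0.06) were the 2 called of 8. Cell wall loosening genes had 3 positive and 6 negative of 19, with XTH31 at -0.97 ± 0.12 and XTH9 at 0.90 ± 0.19. Gibberellin biosynthesis genes had 2 positive and 2 negative of 10, gibberellin signalling genes 1 and 1 of 9, ABA signalling genes 1 and 1 of 23, with ABI4 at 0.75 ± 0.09 and HAI3 at -0.44 ± 0.08, and DNA replication and cell cycle genes 1 and 1 of 16, with RNR1 at -0.37 ± 0.07. ABA and osmotic response genes had 2 negative of 16, ABA biosynthesis genes 1 negative of 8 (NCED9), mitochondrion-encoded genes 1 positive of 8 (ATMG00020 at 0.87 ± 0.13) and ribosomal protein genes 1 negative of 272. The positive call of MCM7 among replication genes was lost without Col-0 water replicate 2 (0.71) or 3 (0.71), Col-0 mannitol replicate 2 (0.65) or 3 (0.68), odr1-2 water replicate 3 (0.62) or odr1-2 mannitol replicate 1 (0.69). The chloroplast call of ATCG00120 was lost without Col-0 water replicate 1 (1.68) or 2 (1.37), Col-0 mannitol replicate 1 (1.53) or 3 (1.53), odr1-2 water replicate 1 (1.44) or 2 (1.71) or odr1-2 mannitol replicate 1 (1.65) or 2 (1.62). The ribosomal call of AT3G14595 was lost without Col-0 water replicate 1 (-0.31), 2 (-0.34) or 3 (-0.33), Col-0 mannitol replicate 2 (-0.26), odr1-2 water replicate 2 (-0.31) or 3 (-0.33) or odr1-2 mannitol replicate 3 (-0.29). The edgeR test called 0 interactions among the 2 ABA catabolism genes, 6 embryo programme transcription factors, 20 photosynthesis genes, 5 jasmonate genes, 3 seed coat markers and the 1 gibberellin deactivation gene. At an unadjusted p under 0.05 it found 1, 2, 2, 0, 0 and 0 of them in that order. DESeq2 and limma-voom called 0 in each of these lists, and the limma-trend fit on TPM called 1 photosynthesis gene.

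The interaction test called 690 genes, 199 positive and 491 negative. Of the 491 negative ones 357 rose and 65 fell with mannitol in Col-0, and of the 199 positive ones 24 rose and 142 fell. The interaction holds the Col-0 response with a minus sign and shares its libraries. Such a split therefore arises in part by construction and does not by itself show a weaker response in odr1-2. Of the 690, 89 reached a 2-fold difference in response, 30 positive and 59 negative. In the limma-trend fit on TPM 106 were positive and 462 negative. Camera called 7 of 21 lists for the interaction and 5 held with an estimated correlation: LEA and seed maturation (adjusted p = 0.0352 with an estimated correlation), seed storage protein and oil body (0.00126), heat shock proteins (0.00465), dormancy regulators (0.0417) and endosperm markers (0.0417). The calls of chloroplast-encoded (adjusted p = 0.151 with an estimated correlation) and lipid mobilisation (0.151) were lost. Adjusted over the list alone, the LEA and seed maturation list had 20 negative interactions, the storage list 2 positive and 14 negative, heat shock proteins 6 positive, endosperm markers 3 negative and lipid mobilisation 6 negative. In the same way ABA and osmotic response had 2 positive and 3 negative, aquaporins 1 positive, cell wall loosening 5 positive, ABA catabolism 1 positive, embryo programme transcription factors 1 negative, gibberellin biosynthesis 3 negative and ribosomal protein genes 0, and the other counts were equal.

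Across genes, which are not independent replicates, the mannitol responses of the 2 genotypes had a Pearson correlation of 0.780 and a Spearman correlation of 0.763 over the 18413 genes tested, with a slope of odr1-2 on Col-0 of 0.738. In both genotypes 2838 genes rose, against 820 if calls were independent, 2840 fell, against 837, and 32 were called in opposite directions. GASA2, GOLS2 and AT1G08170 were among the 5 largest rises, and XTH15, XTH4 and EXO among the 5 largest falls, in both. The genotype differences in water and in mannitol had a Pearson correlation of 0.776, a Spearman correlation of 0.737 and a slope of 0.813. In both media 2700 genes were higher in odr1-2, against 771 if independent, 2452 were lower, against 670, and 47 were called in opposite directions. These pairs of comparisons share no library. Error in the fold changes regressed on lowers both slopes, so neither shows by itself a smaller effect.

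**Figure D4:**
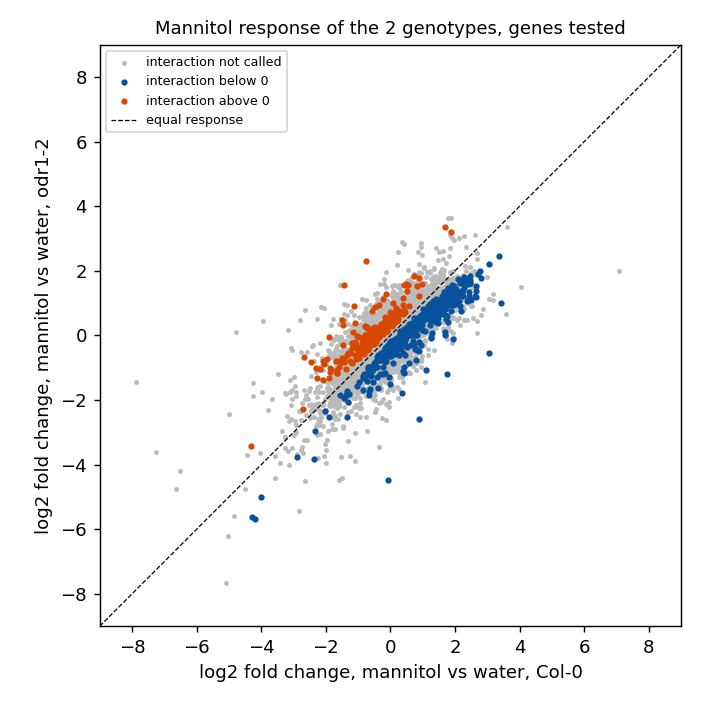
Log2 fold change for mannitol versus water in odr1-2 against that in Col-0, one point per gene tested, with the interaction calls coloured by sign and a dashed line of equal response. Of the 491 negative calls (blue), 398 lie to the right of 0, and of the 199 positive calls (orange), 38 do. This split arises in part by construction, since the interaction holds the Col-0 response with a minus sign.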

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

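The test for non-coding loci, the covariance without abundant genes and the counts of list members under each scaling were chosen only after the result was seen. The results given first are those in which the 2 genotypes differed in their response to mannitol by the interaction term of the edgeR quasi-likelihood test, which 690 genes passed. Of the 50 genes named for the interaction, 46 passed, 30 with a negative and 16 with a positive value. This count is not a rate of success, since all but the genes fixed in advance were chosen among calls. Of the genes fixed in advance, CYP707A2, ABI5, NCED6 and bHLH57 did not pass. By camera 7 lists passed, of which 5 held with an estimated correlation.

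Of 22 LEA and seed maturation genes 18 had a negative interaction and 0 a positive one by edgeR (median -0.43), and of 18 seed storage protein and oil body genes 13 had a negative and 1 a positive one (median -0.50). RAB28 (-0.84), ECP31 (-0.80), PER1 (-0.75), EM6 (-0.44), AT2G18540 (-1.02), AT4G36700 (-0.92) and HSD1 (-1.42) belong here, as do the seed aquaporin genes TIP3;1 (-0.94) and TIP3;2 (-0.85). The call of HSD1 was lost without Col-0 water replicate 1 (-1.41), 2 (-1.32) or 3 (-1.55) or odr1-2 water replicate 2 (-1.40), and in the DESeq2 Wald test (-1.40), limma-voom (-1.36) and limma-trend on TPM (-1.05). GOLS2 lost its call in limma-voom (-0.80). RD29B and GOLS2, of ABA and osmotic response, stood at -1.05 and -0.82, NCED9, of ABA biosynthesis, at -0.73, and HAI3 and ABI4, of ABA signalling, at -0.44 and 0.75. Dormancy regulators had a median of -0.10, with DOG1 at -1.04, MFT at -0.59 and ERF12 at -0.49, and the call of ERF12 was lost without odr1-2 water replicate 3 (-0.42). The call of DOG1 was lost without Col-0 water replicate 1 (-0.96) or 3 (-0.83), in limma-voom (-1.05) and in limma-trend on TPM (-0.50).

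Endosperm markers had a median of -0.24, with EXPA2 at -0.32 and MAN7 at -0.51, and lipid mobilisation genes had a median of -0.11, with PMDH1 at -0.24, MFP2 at -0.23 and PCK1 at -0.20, a list whose call was lost (adjusted p = 0.151 with an estimated correlation in camera). Heat shock protein genes had a median of 0.32, with HSP17.8 at 3.05, HSP17.6C at 1.13 and HSP17.6A at 1.11. Chloroplast-encoded genes had a median of 0.46, with ATCG00120 at 1.67 and ATCG00340 at 1.33, and this list too lost its call (adjusted p = 0.151 with an estimated correlation in camera). The mitochondrion-encoded ATMG00020 stood at 0.87. Gibberellin genes had GA3OX1 at 0.73, GA3OX2 at 0.74, RGA at 0.30, GASA6 at -0.44 and GA20OX2 at -1.50. Cell wall genes had XTH15 at -1.49, XTH31 at -0.97 and XTH9 at 0.90. DNA replication genes had MCM7 at 0.73 and RNR1 at -0.37, and the ribosomal protein gene AT3G14595 had -0.32. The others were FTM1 (2.00), GSTF9 (1.35), YLS5 (1.32), AT4G30470 (1.31), AT2G29310 (-2.42), CYP78A6 (-1.47) and AT5G45670 (-1.45). In limma-voom the calls of HSP17.6C (1.09), ATCG00120 (1.66), ATCG00340 (1.36) and AT3G14595 (-0.32) were lost, and in limma-trend on TPM those of GA3OX1 (0.63), RGA (0.25), MCM7 (0.59), ATCG00120 (0.81) and ATCG00340 (0.45). Some of these calls were also lost when 1 library was left out. That of MCM7 was lost without Col-0 water replicate 2 (0.71) or 3 (0.71), Col-0 mannitol replicate 2 (0.65) or 3 (0.68), odr1-2 water replicate 3 (0.62) or odr1-2 mannitol replicate 1 (0.69). HSP17.6C lost its call without Col-0 water replicate 2 (1.06) or 3 (1.101), Col-0 mannitol replicate 1 (1.08), odr1-2 water replicate 1 (1.12), 2 (1.14) or 3 (1.13) or odr1-2 mannitol replicate 1 (0.99) or 3 (1.08). ATCG00120 lost its call without Col-0 water replicate 1 (1.68) or 2 (1.37), Col-0 mannitol replicate 1 (1.53) or 3 (1.53), odr1-2 water replicate 1 (1.44) or 2 (1.71) or odr1-2 mannitol replicate 1 (1.65) or 2 (1.62). ATCG00340 did so without Col-0 water replicate 1 (1.29), odr1-2 water replicate 2 (1.07) or 3 (1.37) or odr1-2 mannitol replicate 3 (1.21). AT3G14595 did so without Col-0 water replicate 1 (-0.31), 2 (-0.34) or 3 (-0.33), Col-0 mannitol replicate 2 (-0.26), odr1-2 water replicate 2 (-0.31) or 3 (-0.33) or odr1-2 mannitol replicate 3 (-0.29).

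Of 100 regroupings of the 12 libraries into 4 groups of 3, 3 called as many interaction genes as the real grouping with 690, the real one included. The highest other regrouping called 3634, which points to a structure of the samples: regroupings mix groups that differ at many genes, so that this count does not settle whether chance is excluded for the interaction. For the 4 comparisons of 3 libraries with 3, the 10 splits are too few for a share under 0.05. The real split was the 1 that called most each time, with 7695, 8038, 7753 and 6923 genes in fits of those 6 libraries, and the highest other split called 0.

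In the first pattern, odr1-2 in water differed from Col-0 in water along the response of Col-0 to mannitol, with a covariance across genes of 0.146. Both comparisons share the Col-0 water libraries, and 20 simulations with no change gave a mean covariance of 0.0183. The correlation of 0.478 shows nothing by itself, since those simulations gave 0.4995 on average and 0.516 at most. Where the shared libraries enter with opposite signs, as for the Col-0 response and the genotype difference in mannitol, the covariance was still positive at 0.0671, against a highest simulated value of -0.0182, which argues against the shared libraries as the whole cause. Without both maturation lists and the 100 most abundant genes the correlation was 0.471, which decides nothing for the same reason. The covariance with opposite signs was then 0.0649 over the 18283 genes left, so most of it lay in genes other than those removed. Each gene counts equally in a covariance, so removing so few could hardly have lowered it. This test therefore decides little about abundant genes. A seed state in odr1-2 in water that resembles that of osmotic stress, such as slower progress of imbibition, may remain, and was not tested.

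In the second pattern, most maturation and storage genes had a smaller fold change with mannitol in odr1-2. The highest median interaction of the 40 members over 4 scalings was -0.48 and the lowest was -0.52. Over all genes tested the medians ran from -0.051 to -0.012, so these scalings differed little. The choice among the 4 therefore does not account for the pattern, and an error common to them could not have been seen. A ceiling for abundant transcripts stays open, because the upper quartile of the interaction was 0.131 among members under 100 CPM in every group and these were 5 genes, 3 of them below 0. Since these genes started higher in odr1-2 in water, a smaller fold change may go with a higher start, and this cannot be told apart from a weaker response.

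In the third pattern, 112 loci differed by at least 4-fold between the genotypes in both media, 84 higher and 28 lower in odr1-2, among them FUS3, MRD1, IRT3 and, chosen after their values were seen, FWA (-3.29 in water) and BOR4 (3.55). In the order of locus numbers, no excess of neighbouring loci beyond the spread of random sets was seen. In all, 4 pairs lay within 5 tested genes of each other in that order, against a median of 3 in 10000 random sets (permutation p = 0.449). Locus numbers do not always follow position: AT2G08685, 1 of these loci, overlaps AT2G34790. The count can therefore miss loci that lie close together, and linked variation around the mutation stays open. A mannitol-like state cannot be told apart either, with a median Col-0 response of 0.69 in the direction of the genotype difference against a median difference of 2.75. The number of loci annotated other than protein-coding was 15 against a median of 14 in matched sets (permutation p = 0.399). No excess of these loci beyond the spread of the matched sets was seen, and an excess too small for this test stays open. Variants that differ between the 2 seed lines may contribute and were not analysed here. Whether the replicates came from separate seed batches is not known here. In every comparison of the genotypes, a difference between batches therefore cannot be told apart from the genotype.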

How the results depend on the processing

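The added lists and the counts of list members under each scaling were chosen only after the result was seen. No called gene changed direction past its threshold under the alternatives run, and no list called by camera changed direction. For the genotypes in mannitol, camera did not call the embryo programme transcription factors (down, adjusted p = 0.835), whereas fry called them up (adjusted p = 0.0098). The larger side among all calls and the direction of some list medians and counts turned with the scaling, as given with their comparisons. Beyond leaving out libraries, the values that moved were the following. With a fold of at least 2 the calls numbered 1443 for mannitol in Col-0, 1217 for mannitol in odr1-2, 1193 for the genotypes in water, 1255 in mannitol and 89 for the interaction, and with an adjusted p under 0.01 the interaction had 450, as stricter thresholds give by construction. The list tests had 51 calls over the 5 comparisons, 31 with an estimated correlation and 84 with fry, which are different tests. Among genes called in at least 1 of the comparisons the correlation was 0.838 for the mannitol responses and 0.838 for the genotype differences, which is a selection of genes. Without 1 library at a time the calls ran from 6890 to 7841 for mannitol in Col-0, from 6985 to 8199 in odr1-2, from 6145 to 7548 for the genotypes in water, from 6561 to 7427 in mannitol, and from 556 (without Col-0 water replicate 1) to 905 (without Col-0 mannitol replicate 2) for the interaction. In these fits the list tests had 49 to 55 calls, and the correlations ran from 0.757 to 0.769 and from 0.755 to 0.765. The other scalings, filters and tools kept the total count of calls of each comparison within 1.5 times its value, though not each count by direction (positive interactions numbered 106 in limma-trend on TPM against 199), with the interaction at 627 in DESeq2, 647 in limma-voom, 568 in limma-trend on TPM and 793 with total count scaling; the cause was not tested. With replicate number as a block the counts were 7898, 7925, 7265, 7469 and 757. The 18 correlations of deviations between libraries of the same number ran from -0.0264 to 0.0298, so that the numbers do not pair the samples. Over the alternatives run for them, named genes stayed on the same side of the threshold 7885 times, called or not, lost a call 146 times and gained one 10 times. With an estimated correlation, fry or a replicate block, list tests stayed on the same side 258 times, lost a call 21 times and gained one 36 times. At the depth and replicate number of these libraries, simulation recovered 46 of 100 genes with a 1.5-fold interaction, and other depths were not simulated.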

Other observations

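The lists of indolic glucosinolate, aliphatic glucosinolate and clock genes were chosen, and all their tests run, only after CYP83B1, IGMT5, SOT16 and CCA1 had been seen, and the genes named here were chosen after their values were seen.

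Of 8 indolic glucosinolate genes, 7 were lower and 1 higher in odr1-2 in water, with a median log2 fold change of -0.89, among them CYP83B1 (-2.45), IGMT5 (-2.26) and SOT16 (-1.82), while MYB51 was higher (1.66). In mannitol 5 were lower and 2 higher (median -0.86). Mannitol lowered 6 of them in Col-0 and 3 in odr1-2, and the interaction was positive for 4 and negative for 1. No p is given for this list, since 3 of its members prompted it. The 1 tested aliphatic gene, SOT18, was higher in odr1-2 in both media, by 0.84 in water. The lower level in odr1-2 in water was not confined to the members seen first, since 4 of the 5 others were called lower, a count that could have come out otherwise. This describes the pattern and gives no cause for it. Of these 4, MYB34 stood at -0.23 in water but was higher in odr1-2 in mannitol (0.57).

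Of 6 morning clock genes, 5 were higher in odr1-2 in water and 6 in mannitol, with 0 lower in either medium by edgeR, and CCA1 was higher by 2.15 in water and 3.13 in mannitol and LHY by 1.40 and 2.13. No p is given for this list or for the evening list, since CCA1 prompted both. Of 8 evening clock genes, 6 were lower and 1 higher in water, and 4 were lower and 1 higher in mannitol, with ELF4 at -0.99 and -1.28 and GI higher by 0.33 and 0.59. In Col-0 mannitol raised 2 and lowered 2 morning genes and raised 5 evening genes, and in odr1-2 it raised 4 morning genes and raised 6 and lowered 1 evening genes. A shift of clock phase may account for this, but 4 of 8 evening genes called lower in mannitol leave it undecided, since more than 4 were needed beside the 5 of 5 morning genes other than CCA1 that were higher. The hour of sampling is not given per sample.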
